A study of Mus musculus with 9 samples.

How the data were processed

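Liver RNA of 9 samples of C57BL/6 mice in 3 groups of 3 was sequenced. The groups were normal, MCD model and MCD with a high dose of SAR. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit. The genome build was mm9, per the submitters' processing notes. The aligner, the read counter and the annotation are not given in the sources used here, and no strand setting is stated, so antisense and overlapping genes could share reads.

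The authors deposited 2 tables, 1 for model against normal and 1 for SAR against model, and both tables give group means without values per sample. Per the file headers, the signal of a gene in a group is its mean read count divided by DESeq size factors. The deposited fold is the ratio of the 2 group means, with no pseudocount, and the deposited log2 value is the log2 of that fold. The deposited p-values and adjusted p-values are those of the authors' DESeq test, per the names and headers of the deposited tables. Gene IDs were matched to symbols in a reference table of gene names. Of 16521 IDs in the deposited data 16490 had a symbol and 31 did not, and no coordinates were used.

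The design had assumed counts per sample and named a count test for them. The files hold group means, so limma on log2 values, the test named for normalised values, was used instead. Reads per library were first recovered from the group means. A deposited mean is the sum of 3 whole read numbers, each multiplied by a constant of its library, and the means carry 15 digits. The constants of the 3 libraries were found from genes with few reads, and each gene's mean was then solved for the read numbers that give it at that precision. In the normal group 14909 of 14909 genes tried had 1 solution, and in the SAR group 14874 of 14874. For the model group this held for 14519 of 14519 genes in the table with the normal group and for 14664 of 14681 in the table with the SAR group, where the other 17 had none. Solved from both tables together, 16147 of 16147 genes of the model group had 1 solution. Further abundant genes were solved in a later step, with 209 of 230 solved in the normal group and 160 of 182 in the SAR group, and the other 21 and 22 had several solutions. In that step, genes already known were solved alike in 1602 of 1603 and 1508 of 1509 cases. The model group stands in both tables, and 14502 genes solved in each table alone gave identical reads in 14502 cases. Size factors recomputed from the recovered reads differed from the authors' by at most 0.267%. When 2000 deposited means were moved by a tiny relative amount, none of them was solved, whereas 2000 of 2000 unmoved means were. Tested on simulated data, the recovery solved 2718 of 2718 low genes rightly, and it solved 17 of 30 high ones, 17 of them rightly.

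Of 16521 genes 16432 were recovered in all 9 libraries and 89 were not, among them Alb, Mup3, Mat1a, Cyp3a11 and, in the normal group, Scd1. In a comparison with a group where it was not recovered, such a gene is given only as in the authors' deposited table, with no SD or n. The libraries of a group carry no replicate number and are called a, b and c from the largest to the smallest size factor. Reads recovered per library numbered 8556415, 7463542 and 7474680 in the normal group, 12503819, 13320823 and 14939063 in the model group, and 6498227, 6993219 and 6410898 in the SAR group. In the normal and SAR groups these made up 53.2% and 54.0% of the summed group means, since their most abundant genes were not split between libraries.

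Values are reads divided by the authors' size factors within each table. SAR and normal libraries stand in different tables, so their size factors were computed as medians of ratios from the recovered reads. Values of different comparisons are therefore on different scales. Genes with a mean value of at least 10 over the 6 libraries of a comparison were tested with limma, with a trended variance, on log2(value + 1), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 fold changes are on the log2(value + 1) scale and understate the change of genes with few reads. No sample was paired with another. Normalised values are given as mean ± SD over 3 libraries. A gene with 0 reads over a group was compared with a floor of 3 reads over the group, and one with 1 to 3 reads by the ratio with an exact 95% interval. The smallest p of an exact permutation test of 3 against 3 is 0.1, so no such test was run on single genes.

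The groups, the tests, the alternatives, the named genes and 39 gene lists with 850 symbols were fixed before the data were examined. Of these symbols 18 were not in the tables. Some genes stand on several lists, among them Spp1, Mmp12, Lpl, Pdgfrb and Atf3, so the counts of different lists are not independent. Lists with at least 5 measured members, 38 in each comparison, were tested with camera of limma, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over lists, and also with a correlation estimated per list and with fry. In every list called by camera, the median, the mean and the direction of the test had the same sign. Counts of members adjusted over the list alone use the adjustment within the list.

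The rule for named genes took, in each comparison, the 6 largest log2 rises and the 6 largest falls among genes that passed, had a mean value of at least 100 and did not overlap between the groups, passing over symbols that start with Gm or end with Rik. To these it added up to 3 members of each list with the smallest p. It also added, whatever their p, Scd1, Fasn, Cyp7a1, Cyp8b1, Fgf21, Cpt1a, Cd36, Plin2, Col1a1, Acta2, Timp1, Tnf, Il1b, Ccl2, Gpbar1, Nr1h4, Nr0b2, Pemt and Mat1a. Of genes that moved back, the 6 per direction with the largest smaller change were named. Further genes were singled out after the values were seen, and the text says so where they appear.

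Alternatives were pseudocounts of 0.1 and 10, no filter, recomputed size factors, all 9 libraries in 1 fit, each library left out in turn, a threshold of 0.01 and a minimum fold of 2. Alternatives chosen after seeing the data were voom on the recovered reads, the trimmed mean of M-values (trims of 30% and 5%), a value of at least 10 in at least 3 libraries, the authors' deposited test, and the fit without normal library c and model library c. The gene test and the list test were tested on simulated data for each comparison, with 100 genes changed per fold size. In these data the list test recovered 4 of 4 changed lists in each comparison. The simulated genes were drawn independently of each other, so this result cannot show how the list test acts on lists of correlated genes. No simulated library stood apart from its group, and the share of genes changed was set, not taken from the data. The simulated percentages of genes called therefore do not give the power of the real comparisons and do not rank them. The analysis used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.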

Results

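Total RNA of the liver was sequenced in 9 samples from C57BL/6 mice. The methionine-choline-deficient (MCD) diet lacks 2 nutrients the liver needs to export fat, and it is widely used to induce fatty liver with inflammation and fibrosis in rodents. Mice given this diet yielded 6 of the samples. In 3 of these the mice had also been treated with sarsasapogenin (SAR), a steroidal sapogenin of the rhizome of Anemarrhena asphodeloides. The groups were thus normal (n = 3), MCD model (n = 3) and MCD with a high dose of SAR (n = 3), whose amount the labels do not state. The design text says that mice were divided among the groups at random, and the normal group was given saline. No label says which samples came from separate mice, so the p-values measure only the spread between these samples, which may be technical. Reads assigned to genes came to 12503819, 13320823 and 14939063 in the model libraries. The 3 normal libraries held between 43105721 and 45937649 reads together, and the 3 SAR libraries between 36145567 and 37420219. These are ranges because the reads of the most abundant genes could not be divided among the libraries of these groups. The letters a, b and c order the libraries of a group by size factor and do not correspond to the replicate numbers of the labels.

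Of the 9 libraries, normal library c and model library c stood apart from the other two of their groups. Across genes, which are not independent replicates, log2 values of normal library c correlated at 0.934 and 0.925 with those of normal libraries a and b, against 0.977 between these 2. For model library c the correlations were 0.928 and 0.941, against 0.980 between model libraries a and b, and the SAR libraries correlated at 0.963 to 0.970. On a scale common to the 9 libraries, Lcn2 (ENSMUSG00000026822), which encodes an acute phase protein, stood at 41029 normalised reads in normal library c against 90.3 and 262 in the other two. Mup11 (ENSMUSG00000073834), a major urinary protein gene more active in male liver, stood at 52.9 there against 9827 and 11458. Neutrophil markers lay a median of 5.42 higher (log2, SE 0.77, 16 genes) in normal library c than in the other normal libraries, and male-biased liver genes differed by a median of -3.88 (SE 0.87, 16 genes). In model library c, the collagen gene Col1a1 stood at 687 normalised reads against 4915 and 4033, cholangiocyte markers differed by a median of -2.62 (log2, SE 0.28, 17 genes), and cholesterol synthesis genes lay a median of 1.41 higher (SE 0.15, 26 genes). Mmp12, a macrophage gene, stood at 2952 there against 2571 and 2411. Here and below, the SE of such a median is taken over the genes of the list, not over libraries. Genes of a list are correlated, so this SE can understate the uncertainty. These library differences were singled out after the values were seen.

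**Figure D1:**
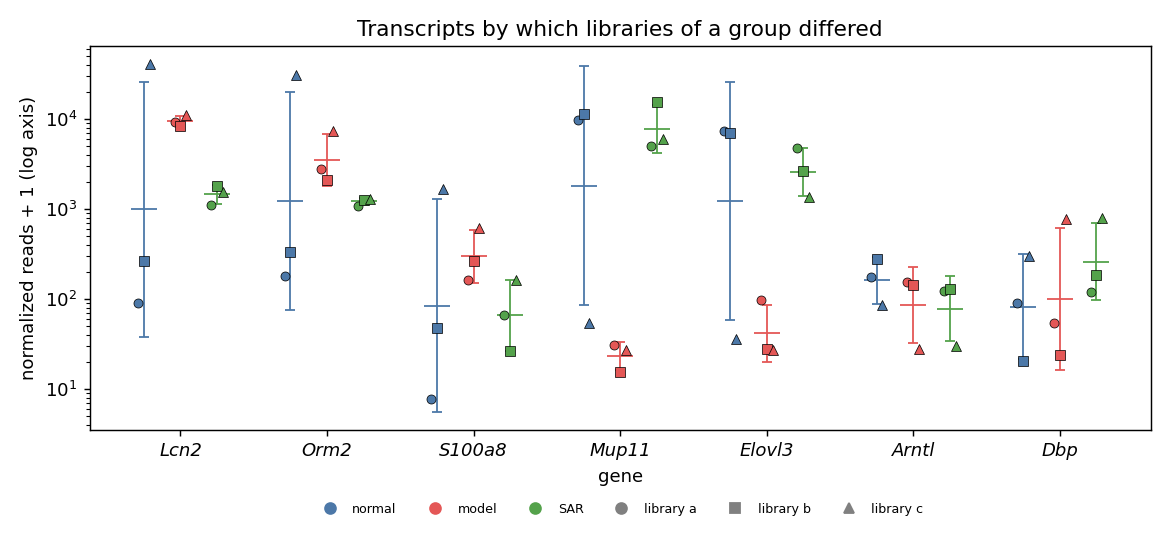
Normalised reads plus 1 (log axis, scale common to the 9 libraries) of 7 genes in the normal, model and SAR groups, with 1 point per library shaped by its letter, a line at the mean of the log2 values and bars of ± 1 SD on the log scale (n = 3). Normal library c holds 41029 reads of Lcn2 and 52.9 of Mup11, outside the range of the other two normal libraries.

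The model group was compared with the normal group to find the liver transcripts that differed with the MCD diet. Macrophage transcripts were among the largest rises. Mmp12 (ENSMUSG00000049723), the macrophage elastase, rose from 8.76 ± 2.60 to 2935 ± 315 normalised reads (SD, n = 3), a log2 fold change of 8.26 (SE 0.22, limma Benjamini-Hochberg adjusted p = 3.40e-06). Gpnmb (ENSMUSG00000029816), a glycoprotein of lipid-laden macrophages, rose from 13.6 ± 1.90 to 3088 ± 643 (log2 7.71, SE 0.20, limma adjusted p = 3.40e-06). The stress response gene Nupr1 (ENSMUSG00000030717) rose from 13.6 ± 3.81 to 695 ± 29.2 (log2 5.61, SE 0.23, limma adjusted p = 6.85e-05). Cyp8b1 (ENSMUSG00000050445), the sterol hydroxylase required for cholic acid, fell from 11647 ± 6091 to 852 ± 245 (log2 -3.63, SE 0.48, limma adjusted p = 0.00228).

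Members of 6 immune lists rose, and the list of Kupffer cell and macrophage markers went both ways. Of its 18 members 8 rose, 4 fell and 6 did not pass (8 and 5 adjusted over the list alone), and the list was not called (camera in limma, adjusted p = 0.467). Among 19 markers of lipid-associated and recruited macrophages, 16 rose and 3 did not pass, with 16 higher adjusted over the list alone. The integrin gene Itgax rose from 17.6 ± 4.21 to 569 ± 57.8 normalised reads (SD, n = 3), a log2 fold change of 4.96 (SE 0.24, limma adjusted p = 1.20e-04). Of 18 T and NK cell markers, 16 rose (17 adjusted over the list alone), among them the interleukin 7 receptor gene Il7r (log2 2.80, SE 0.21, limma adjusted p = 6.11e-04) and Cd8a (log2 3.73, SE 0.47, limma adjusted p = 0.0021). Antigen presentation genes rose in 14 of 17 cases (14 adjusted over the list alone), with the class II invariant chain Cd74 going from 974 ± 80.5 to 5555 ± 1059 (log2 2.50, SE 0.19, limma adjusted p = 5.85e-04). Of 27 inflammatory cytokine, chemokine and signalling genes, 18 rose (20 adjusted over the list alone), including Casp1 (log2 2.43, SE 0.23, limma adjusted p = 0.00102), Tnf (log2 3.48, SE 0.59, limma adjusted p = 0.00496) and the monocyte chemoattractant Ccl2 (log2 4.83, SE 0.76, limma adjusted p = 0.00399). Il1b stood at 83.2 ± 13.1 and 73.5 ± 9.93 and did not pass (limma adjusted p = 0.566). Interferon response genes rose in 15 of 24 cases (17 higher and 1 lower adjusted over the list alone), led by Gbp3, Oas1a and Irf1. Camera is limma's test of a list against all other genes. It gave adjusted p-values of 2.65e-11 for the recruited macrophage list, 2.33e-07 for T and NK cells, 1.72e-07 for antigen presentation, 2.65e-07 for inflammation and 1.25e-04 for interferon. None of these 5 calls held with an estimated correlation, where their adjusted p-values were 0.222, 0.222, 0.237, 0.237 and 0.39. Of 7 B and plasma cell markers 2 rose and 5 did not pass (2 adjusted over the list alone; camera in limma, adjusted p = 0.0255, and adjusted p = 0.325 with an estimated correlation). This call was lost without model library c (camera adjusted p = 0.0709).

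Neutrophil and acute phase transcripts were spread widely within the normal group. Of 16 neutrophil markers, 1 rose (Csf3r) and 15 did not pass, and the 16 did not pass adjusted over the list alone, while with normal library c left out 13 of the 16 rose. Of 13 acute phase genes recovered, 4 fell and 9 did not pass (3 lower adjusted over the list alone), including C-reactive protein, Crp, from 7819 ± 425 to 2475 ± 1258 normalised reads (SD, n = 3, log2 -1.77, SE 0.33, limma adjusted p = 0.00664). The other 13 listed did not pass in the authors' deposited table. Without normal library c, 6 of the 13 recovered rose and 4 fell. Normal library c lay a median of 2.23 above the other normal libraries over these acute phase genes (log2, SE 0.86). Csf3r was called with all libraries (limma adjusted p = 0.0226) but not without normal library a (0.0680), normal library b (0.0663), model library a (0.0914) or model library b (0.0749).

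Matrix, bile duct, proliferation and stress transcripts also rose. Of 32 extracellular matrix genes, 27 rose and 5 did not pass (28 higher and 1 lower adjusted over the list alone), including the intermediate filament gene Vim, from 527 ± 187 to 4489.7 ± 1232 normalised reads (SD, n = 3, log2 3.11, SE 0.31, limma adjusted p = 0.00109). Col1a1 (ENSMUSG00000001506) rose from 105 ± 107 to 3559 ± 2468 (log2 5.99, SE 1.48, limma adjusted p = 0.0169), a call lost without model library a (0.0718) or model library b (0.0629). Acta2, a marker of activated stellate cells, stood at 131 ± 123 and 331 ± 178 and did not pass (limma adjusted p = 0.136). Timp1 (ENSMUSG00000001131), an inhibitor of matrix metalloproteinases, had 2 reads over the normal group and 905 over the model group, a ratio of 329 with a 95% exact interval of 90.7 to 2718. Stellate cell and fibroblast markers rose in 9 of 18 cases (9 adjusted over the list alone), led by Pdgfrb, Cygb and Des, and cholangiocyte markers in 13 of 17 (14 adjusted over the list alone), led by Spp1 (log2 3.32, SE 0.61, limma adjusted p = 0.00634). Spp1 is also on the list of recruited macrophage markers, and Pdgfrb is also on that of matrix genes. Cell cycle genes rose in 20 of 24 cases (21 adjusted over the list alone), among them Mcm6, Cdk1 and Birc5, and 13 of 22 p53 target and cell death genes rose (13 adjusted over the list alone), among them Bax and Gdf15. Of 23 amino acid and integrated stress response genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone), and Atf3 went from 65.0 ± 7.38 to 811 ± 151 (log2 3.61, SE 0.18, limma adjusted p = 1.61e-04). Of 28 NRF2 target genes, 13 rose and 3 fell (14 and 3 adjusted over the list alone), including the glutathione transferase gene Gstm3 (log2 4.21, SE 0.20, limma adjusted p = 1.20e-04). The camera adjusted p-values were 2.44e-09 for matrix, 7.36e-04 for stellate cells, 1.50e-04 for cholangiocytes, 2.84e-06 for cell cycle, 9.50e-04 for p53, 6.58e-04 for the stress response and 0.0149 for NRF2. With an estimated correlation the adjusted p-values of these 7 lists ran from 0.325 to 0.573. Within the model group, library c differed from the other two by a median of -1.42 (log2, SE 0.22) over matrix genes, -2.62 (SE 0.28) over cholangiocyte markers and -1.02 (SE 0.28) over cell cycle genes. Within the normal group, library c differed by -1.65 (SE 0.32) over matrix genes, -1.54 (SE 0.25) over stellate cell markers and 0.95 (SE 0.28) over cell cycle genes.

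Part of the genes in 6 lists of hepatocyte functions fell. Of 24 bile acid synthesis and transport genes, 15 fell and 1 rose (15 and 1 adjusted over the list alone). Cyp7a1 (ENSMUSG00000028240), the rate-limiting enzyme of bile acid synthesis, fell from 600.1 ± 88.2 to 142 ± 112 normalised reads (SD, n = 3, log2 -2.33, SE 0.47, limma adjusted p = 0.00843). Baat, which conjugates bile acids to amino acids, fell from 4439 ± 253 to 1671 ± 277 (log2 -1.42, SE 0.17, limma adjusted p = 0.00197). Acox2 and Slc27a5 fell as well. Methionine, choline and one-carbon genes fell in 13 of 22 cases and rose in 2 (13 and 2 adjusted over the list alone), including Aldh7a1 and the transsulfuration genes Cbs (log2 -1.46, SE 0.22, limma adjusted p = 0.00349) and Cth (log2 -2.17, SE 0.33, limma adjusted p = 0.0037). Mat1a, which makes S-adenosylmethionine, could not be resolved per library, and in the authors' deposited table its mean was 210281 in the normal group and 32928 in the model group, a fold of 0.157 (adjusted p = 1.31e-05 by the authors' DESeq test). Pemt, the phosphatidylcholine synthase that draws on methionine, stood at 3484 ± 563 and 2807 ± 1688 and did not pass (limma adjusted p = 0.361). Endoplasmic reticulum chaperones fell in 11 of 20 cases (11 adjusted over the list alone), nuclear genes of the respiratory chain in 13 of 25 (15 adjusted over the list alone) and hepatocyte secreted and identity genes in 7 of 9 (7 adjusted over the list alone). The other 11 of these 20 identity genes were not resolved per library, and by the authors' deposited table, 5 of them were lower and 6 did not pass, with folds of 0.877 for albumin, Alb, and 0.495 for Rbp4 (adjusted p = 0.862 and 0.00229 by the authors' DESeq test). Glucose and glycogen genes fell in 11 of 20 cases and rose in 2 (11 and 2 adjusted over the list alone), with the glycogen-targeting subunit Ppp1r3c going from 623 ± 177 to 48.8 ± 17.3 (log2 -3.67, SE 0.29, limma adjusted p = 7.30e-04). The camera adjusted p-values were 2.63e-05 for bile acids, 0.00115 for methionine and choline, 3.23e-05 for chaperones, 2.99e-04 for the respiratory chain, 1.0e-04 for hepatocyte identity and 0.00153 for glucose. With an estimated correlation the adjusted p-values of these 6 lists ran from 0.325 to 0.613.

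Lipid genes moved in both directions. Of 24 fatty acid oxidation genes and PPARalpha targets, 12 fell and 2 rose (13 and 2 adjusted over the list alone; camera adjusted p = 0.00123, and adjusted p = 0.613 with an estimated correlation). Over these genes, model library c lay a median of 0.9999 (log2, SE 0.11) above the other model libraries, and normal library c differed by -0.60 (SE 0.33). Cyp4a32 fell, but its reads are shared with near-identical relatives. Acadvl, an acyl-CoA dehydrogenase, fell from 3044 ± 338 to 764 ± 345 normalised reads (SD, n = 3, log2 -2.08, SE 0.29, limma adjusted p = 0.0028), and the hepatokine gene Fgf21 rose from 158 ± 74.1 to 643 ± 154 (log2 2.14, SE 0.40, limma adjusted p = 0.00681). Cpt1a, which controls fatty acid entry into mitochondria, fell from 14615 ± 1601 to 6400.1 ± 2934 (log2 -1.28, SE 0.35, limma adjusted p = 0.024), a call lost without normal library a (0.0768), normal library b (0.0765), model library a (0.0757) or model library b (0.106). Of 21 lipid droplet and fatty acid uptake genes, 5 rose and 4 fell (5 and 6 adjusted over the list alone). Lipoprotein lipase, Lpl, rose from 428 ± 195 to 8459 ± 1607 (log2 4.42, SE 0.38, limma adjusted p = 8.07e-04), and so did the fatty acid translocase Cd36 (log2 1.59, SE 0.32, limma adjusted p = 0.00832). Plin2, a lipid droplet coat protein gene, stood at 18902 ± 6776 and 13003 ± 5686 and did not pass (limma adjusted p = 0.327). Of 16 lipogenesis genes, 5 fell and 1 rose (4 and 1 adjusted over the list alone), with Lpin1 falling (log2 -2.61, SE 0.21, limma adjusted p = 7.54e-04), Srebf1 rising (log2 1.65, SE 0.29, limma adjusted p = 0.00559) and Fasn at 963 ± 81.2 and 993 ± 411. Scd1, the stearoyl-CoA desaturase gene, was not resolved per library. In the authors' deposited table its mean was 23038 in the normal group and 5605 in the model group, with an adjusted p of 0.234. Nr1h4, the bile acid receptor FXR, fell (log2 -0.93, SE 0.27, limma adjusted p = 0.0284), but not without normal library a (0.0596), b (0.0608) or c (0.0613) or model library a (0.102) or b (0.106), and its target Nr0b2 stood at 455 ± 188 and 613 ± 169. Gpbar1, the membrane bile acid receptor gene, had 6 reads over the model group and 0 over the normal group, too few for a test.

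Male-biased liver genes fell in 10 of 18 cases and 8 did not pass (11 lower adjusted over the list alone; camera adjusted p = 3.06e-05, and adjusted p = 0.39 with an estimated correlation). Without normal library c, which differed by a median of -3.88 from the other normal libraries over these genes, 17 of the 18 fell. The cytochrome gene Cyp2d9 fell from 26319 ± 13065 to 1622 ± 815 normalised reads (SD, n = 3, log2 -4.00, SE 0.55, limma adjusted p = 0.00265) and the growth factor receptor gene Egfr from 9510.0 ± 1901 to 2031 ± 313 (log2 -2.22, SE 0.22, limma adjusted p = 0.00109). The largest falls met by the selection rule were those of Mup15, Mup12, Mup11, Mup9 and Mup22, with log2 fold changes of -8.17, -7.02, -6.29, -5.26 and -4.65, and of the organic anion transporter gene Slco1a1 (log2 -4.76, SE 1.26, limma adjusted p = 0.0217). Without normal library a or b or model library a or b, the calls of the 5 Mup genes were lost (limma adjusted p from 0.0822 to 0.143) and so was that of Slco1a1 (0.0683 to 0.0769). Without model library c, the calls of Mup12 (limma adjusted p = 0.0801), Mup11 (0.0538) and Mup22 (0.0520) were lost too. Mup genes share reads with near-identical copies, so the values of single members are uncertain. Among the largest rises, Vmn2r3 (ENSMUSG00000091572), a vomeronasal receptor gene, had 0 reads over the normal group and 869 over the model group, at least 210.4-fold higher against a floor of 3 reads over the group. Cyp2a4, which shares reads with a close relative and is uncertain for that reason, had 1 read over the normal group against 2707, a ratio of 1966 with a 95% exact interval of 353 to 77677. Scube1 rose from 2.35 ± 3.19 to 209.9 ± 132 (log2 6.16, SE 0.85, limma adjusted p = 0.00268). These intervals and floors cover counting error only.

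Over 12575 genes tested, 4907 differed between the model and normal groups by limma with Benjamini-Hochberg adjustment, 2507 higher and 2400 lower in the model, and 2929 of them by at least 2-fold. The groups did not overlap in 6771 genes (53.8%), against 10% by chance. The authors' deposited test gave 3847 genes an adjusted p under 0.05, and 3597 of these were called in the same direction here. Without normal library c and model library c the count was 7346, whereas it was 2918 without normal library a, 2652 without model library a and 2435 without model library b. In simulated data for this comparison, 29% of genes changed 2-fold and 90% of those changed 4-fold were called. Far fewer genes changed in those data than were called here, so these percentages do not give the power of the real comparison.

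**Figure D2:**
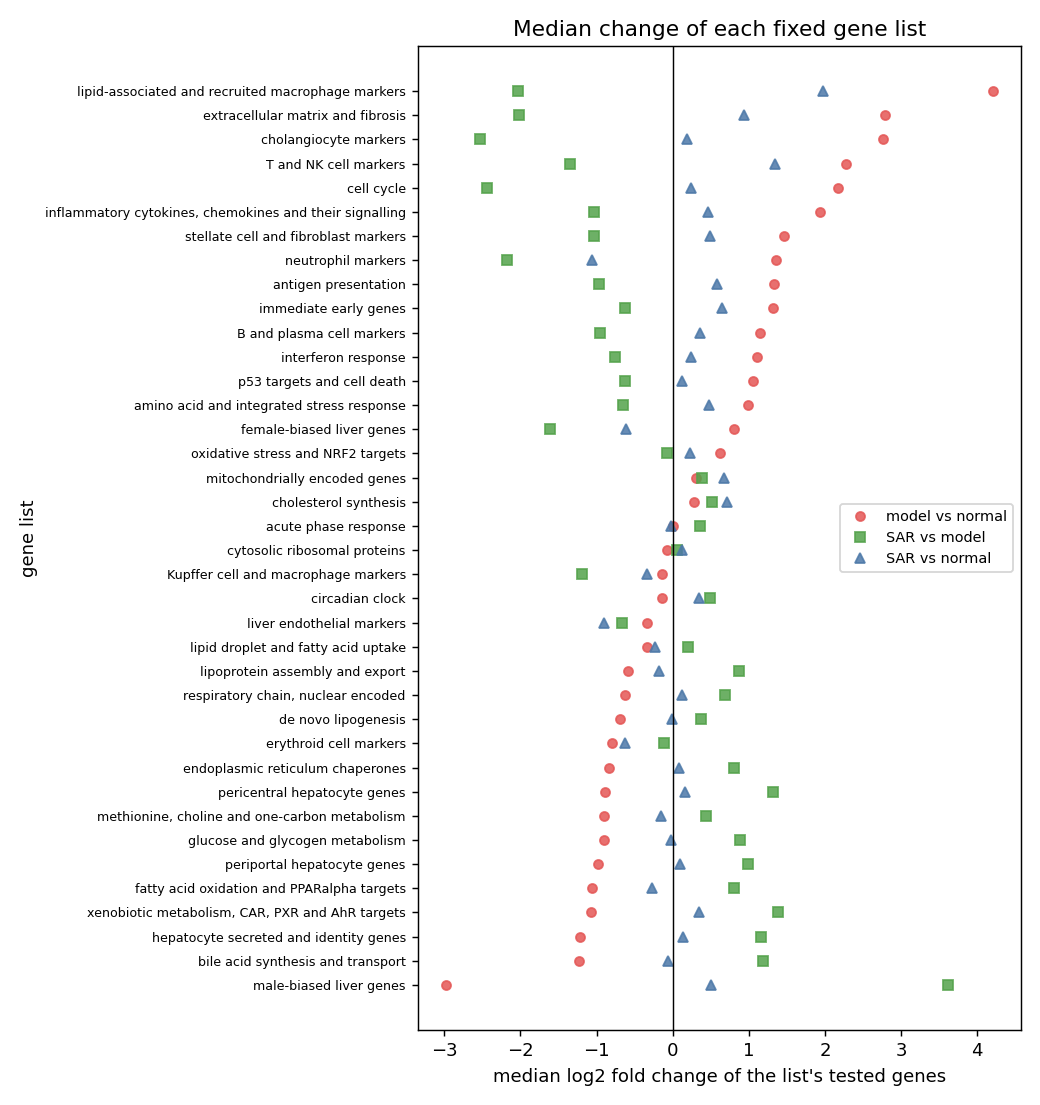
Median log2 fold change of the tested members of each gene list, with 1 marker per list for each of the 3 comparisons. The median of the extracellular matrix list was 2.79 in the model against the normal group and -2.02 with SAR against the model.

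The SAR group was compared with the model group to find the liver transcripts that differed with SAR under the same diet. Major urinary protein transcripts showed the largest rises, and macrophage and matrix transcripts fell. Mup7 (ENSMUSG00000073842) rose from 7.97 ± 0.667 to 17796 ± 13266 normalised reads (SD, n = 3, log2 10.52, SE 0.61, limma Benjamini-Hochberg adjusted p = 5.26e-05), and Slco1a1 (ENSMUSG00000041698) rose from 49.7 ± 27.6 to 2581 ± 439 (log2 5.79, SE 0.33, limma adjusted p = 5.26e-05). Cyp8b1 rose from 782 ± 226 to 7302 ± 836 (log2 3.26, SE 0.24, limma adjusted p = 1.82e-04). Mmp12 fell from 2691 ± 270.4 to 657 ± 94.7 (log2 -2.04, SE 0.17, limma adjusted p = 2.84e-04). Values of this comparison are on its own scale, so the model means differ slightly from those above.

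All 17 male-biased liver genes tested rose, and 17 did so adjusted over the list alone. The camera test of limma gave this list an adjusted p of 2.55e-16. It kept its call with an estimated correlation (camera in limma, adjusted p = 0.0283), alone among the 32 lists called. That estimate was -0.0006 in this comparison, against 0.542 in model against normal and 0.544 in SAR against normal. The kept call thus rests on a low estimate from 6 libraries. Beside Mup7, the rises met by the selection rule were Mup17, Mup15, Mup19, Mup11 and Mup12, with log2 fold changes of 9.04, 8.91, 8.63, 8.39 and 8.22 and limma adjusted p-values of 3.40e-04, 4.09e-05, 5.77e-05, 4.09e-05 and 8.21e-06. Reads of these near-identical genes may be split unevenly among the copies, so single members are uncertain. Mup3 was not resolved per library, and the authors' deposited table gave it a fold of 35.8. Cyp7b1, an oxysterol hydroxylase more active in males, rose from 151 ± 30.2 to 1989.5 ± 967 normalised reads (SD, n = 3, log2 3.62, SE 0.31, limma adjusted p = 3.77e-04).

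Part of the genes in 7 lists of hepatocyte functions rose. Of 24 bile acid synthesis and transport genes, 19 rose and 1 fell (20 and 1 adjusted over the list alone), and Nr0b2 went from 562 ± 155 to 1459 ± 98.04 normalised reads (SD, n = 3, log2 1.41, SE 0.22, limma adjusted p = 0.00298). Nr1h4 rose from 904 ± 340.2 to 1923 ± 292 (log2 1.14, SE 0.25, limma adjusted p = 0.0115), a call lost without model library b (0.0551). Cyp7a1 stood at 129.99 ± 101 and 433 ± 344 and did not pass (limma adjusted p = 0.094). Of 20 endoplasmic reticulum chaperones 11 rose (19 adjusted over the list alone), led by Herpud1, from 3136 ± 704 to 10186 ± 2677 (log2 1.69, SE 0.27, limma adjusted p = 0.00339). Nuclear genes of the respiratory chain rose in 15 of 26 cases (20 adjusted over the list alone), hepatocyte secreted and identity genes in 10 of 11 (11 adjusted over the list alone), and methionine, choline and one-carbon genes in 9 of 25 (9 adjusted over the list alone), among them Aldh7a1, Sardh and Mthfd1. Of the 9 identity genes not resolved per library, 7 were higher in the authors' deposited table and 2, Ahsg and Trf, did not pass. Mat1a had a fold of 1.80 there and did not pass (adjusted p = 0.394 by the authors' DESeq test). Of 20 glucose and glycogen genes 10 rose and 2 fell (12 and 3 adjusted over the list alone), with Ppp1r3b (log2 2.76, SE 0.28, limma adjusted p = 6.46e-04) and Pygl rising and Irs2 falling (log2 -1.09, SE 0.15, limma adjusted p = 0.00204). Of 24 xenobiotic metabolism genes 12 rose and 2 fell (13 and 3 adjusted over the list alone), including Ces2a, from 217 ± 99.4 to 3417 ± 301 (log2 4.06, SE 0.27, limma adjusted p = 1.21e-04), and in the authors' deposited table Cyp3a11 had a fold of 7.56. Model library c lay a median of 1.42 above the other model libraries over the xenobiotic genes (log2, SE 0.50). The camera adjusted p-values were 5.62e-09 for bile acids, 4.64e-07 for chaperones, 2.62e-07 for the respiratory chain, 8.46e-07 for hepatocyte identity, 0.00118 for methionine and choline, 5.38e-04 for glucose and 0.00142 for xenobiotics. With an estimated correlation the adjusted p-values of these 7 lists ran from 0.328 to 0.456.

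Lipid genes again divided. Of 24 fatty acid oxidation genes and PPARalpha targets, 10 rose and 3 fell (13 and 3 adjusted over the list alone; camera adjusted p = 0.00323, and adjusted p = 0.583 with an estimated correlation). Model library c lay a median of 0.9999 (log2, SE 0.11) above the other model libraries over these genes. Cpt2 rose (log2 1.06, SE 0.19, limma adjusted p = 0.00511), whereas Pdk4, a kinase that restrains glucose oxidation, fell (log2 -2.70, SE 0.39, limma adjusted p = 0.00239) and Fgf21 fell from 591 ± 146 to 174 ± 116 normalised reads (SD, n = 3, log2 -1.92, SE 0.40, limma adjusted p = 0.00946). Cpt1a stood at 5862 ± 2651 and 6596 ± 1338 and did not pass (limma adjusted p = 0.599). Among 21 lipid droplet and fatty acid uptake genes 6 fell and 3 rose (6 and 5 adjusted over the list alone). Cidec, which promotes growth of lipid droplets, fell from 1718 ± 448 to 263 ± 55.8 (log2 -2.69, SE 0.23, limma adjusted p = 3.55e-04), and Lpl from 7766 ± 1525 to 2065 ± 685 (log2 -1.94, SE 0.27, limma adjusted p = 0.00194). Cd36 fell (log2 -0.65, SE 0.21, limma adjusted p = 0.0483), a call lost without model library b or c or SAR library a, b or c (limma adjusted p from 0.0544 to 0.123), and Plin2 stood at 11909.5 ± 5133 and 8688 ± 1506 (limma adjusted p = 0.406). Of 18 lipoprotein genes 8 rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.00323, and adjusted p = 0.488 with an estimated correlation). Apoa4 fell from 4176 ± 650.2 to 554 ± 150.3 (log2 -2.94, SE 0.23, limma adjusted p = 2.27e-04) and hepatic lipase, Lipc, rose (log2 1.86, SE 0.25, limma adjusted p = 0.00175). Of 17 lipogenesis genes 5 rose and 12 did not pass (6 higher adjusted over the list alone), the risers including Lpin1, Me1 and Mlxipl. Fasn stood at 909 ± 370.2 and 1349 ± 237 (limma adjusted p = 0.104), Scd1 at 5132 ± 2906 and 4899.9 ± 2725 (0.933) and Pemt at 2569 ± 1529 and 3800.2 ± 109.9 (0.15).

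Immune and matrix transcripts fell. Of 19 recruited macrophage markers 18 fell (18 adjusted over the list alone). Itgax fell from 522 ± 54.2 to 136 ± 35.3 normalised reads (SD, n = 3, log2 -1.97, SE 0.22, limma adjusted p = 9.95e-04), and the chemokine receptor gene Ccr2 fell from 464 ± 48.8 to 109 ± 36.5 (log2 -2.13, SE 0.24, limma adjusted p = 9.95e-04). Kupffer cell and macrophage markers fell in 9 of 17 cases (9 adjusted over the list alone), including Cd68 (log2 -1.96, SE 0.18, limma adjusted p = 4.53e-04). Neutrophil markers fell in 10 of 16 cases (12 adjusted over the list alone), led by Cxcr2 and Csf3r, and T and NK cell markers in 8 of 18 (15 adjusted over the list alone), led by Il7r. Antigen presentation genes fell in 12 of 16 cases (14 adjusted over the list alone), and inflammatory genes in 15 of 27 (16 adjusted over the list alone), led by Cxcl14, Cd14 and Il1rn. Of 24 interferon genes 11 fell and 1 rose (14 and 1 adjusted over the list alone). Lcn2 fell from 9687 ± 1350.1 to 1529.6 ± 359 (log2 -2.68, SE 0.23, limma adjusted p = 3.55e-04) and Ccl2 from 88.8 ± 24.8 to 17.8 ± 7.64 (log2 -2.31, SE 0.40, limma adjusted p = 0.00479). Tnf at 33.1 ± 11.9 and 16.0 ± 7.98 (limma adjusted p = 0.139) and Il1b at 67.4 ± 9.58 and 44.4 ± 20.05 (0.162) did not pass. Of 7 B and plasma cell markers 2 fell (2 adjusted over the list alone; camera in limma, adjusted p = 0.0276, and adjusted p = 0.424 with an estimated correlation), a call lost without model library c (0.0879) or SAR library b (0.0578). Of 20 acute phase genes 7 rose and 3 fell (7 and 3 adjusted over the list alone). The camera adjusted p-values were 7.91e-12 for recruited macrophages, 1.76e-04 for Kupffer cells, 4.95e-05 for neutrophils, 3.68e-05 for T and NK cells, 4.13e-06 for antigen presentation, 2.38e-07 for inflammation and 2.89e-04 for interferon. With an estimated correlation the adjusted p-values of these 7 lists ran from 0.328 to 0.434. Model library c lay a median of 1.16 (log2, SE 0.35) above the other model libraries over the neutrophil markers, and SAR library c a median of 0.99 (SE 0.43) above the other SAR libraries.

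Of 32 matrix genes 28 fell and 4 did not pass (30 lower adjusted over the list alone). Beside Mmp12, Col4a1 fell from 2119 ± 662 to 405 ± 74.3 normalised reads (SD, n = 3, log2 -2.35, SE 0.25, limma adjusted p = 9.08e-04). Timp1 fell from 228 ± 152 to 35.0 ± 1.09 (log2 -2.37, SE 0.52, limma adjusted p = 0.0114) and Acta2 from 304 ± 164 to 57.8 ± 22.0 (log2 -2.24, SE 0.47, limma adjusted p = 0.00978). Col1a1 fell from 3272 ± 2271 to 352 ± 243 (log2 -2.99, SE 0.71, limma adjusted p = 0.0154), but not without model library a (0.0573), model library b (0.0602), SAR library b (0.0668) or SAR library c (0.0600). Stellate cell and fibroblast markers fell in 12 of 18 cases (12 adjusted over the list alone), led by Rgs5, Dcn and Pdgfra, and cholangiocyte markers in 11 of 17 (13 adjusted over the list alone), led by Cd24a (log2 -2.21, SE 0.47, limma adjusted p = 0.0104). Cell cycle genes fell in 19 of 24 cases (19 lower and 1 higher adjusted over the list alone), led by Mcm2, Ccnb1 and Top2a. Immediate early genes fell in 8 of 19 cases (9 adjusted over the list alone), led by Atf3, Myc and Klf6, and p53 targets in 5 of 22 (5 adjusted over the list alone). Of 23 integrated stress response genes 6 fell and 1 rose (6 and 1 adjusted over the list alone), led by Atf3 and Pck2. Nupr1 fell from 637 ± 25.6 to 59.4 ± 53.9 (log2 -3.76, SE 0.49, limma adjusted p = 0.00154). The camera adjusted p-values were 1.48e-11 for matrix, 4.95e-05 for stellate cells, 6.47e-05 for cholangiocytes, 8.74e-09 for cell cycle, 5.38e-04 for immediate early genes, 0.00323 for p53 and 0.00276 for the stress response. With an estimated correlation the adjusted p-values of these 7 lists ran from 0.328 to 0.445. Model library c differed from the other model libraries by a median of -1.42 (log2, SE 0.22) over matrix genes, -2.62 (SE 0.28) over cholangiocyte markers and -1.02 (SE 0.28) over cell cycle genes. SAR library c differed from the other SAR libraries by a median of -0.59 (SE 0.13) over matrix genes and -0.67 (SE 0.30) over cholangiocyte markers. The largest falls met by the selection rule were those of Vmn2r3, with 0 reads over the SAR group and at least 176.6-fold lower than in the model, Nrg1 (log2 -4.96, SE 0.68, limma adjusted p = 0.00194), Ly6d (log2 -4.38, SE 0.39, limma adjusted p = 3.79e-04), Mmp7, Plat and Fam83a. Mmp7 (log2 -4.31, SE 1.10, limma adjusted p = 0.0199) lost its call without model library a or b or SAR library b or c (limma adjusted p from 0.0633 to 0.0813). Gpbar1 had 0 reads over the SAR group.

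Over 12472 genes tested, 3663 differed between the SAR and model groups by limma with Benjamini-Hochberg adjustment, 1648 higher and 2015 lower with SAR, and 2285 of them by at least 2-fold (649 higher and 1636 lower). The groups did not overlap in 5651 genes (45.3%), against 10% by chance. The authors' deposited test gave 2696 genes an adjusted p under 0.05, of which 2567 were called in the same direction here. Without model library c the count was 5159, but it was 1670 without model library a, 1544 without model library b, 1804 without SAR library b and 2248 without SAR library c. In simulated data for this comparison, 51% of genes changed 2-fold and 90% of those changed 4-fold were called, again with far fewer genes changed than were called here.

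**Figure D3:**
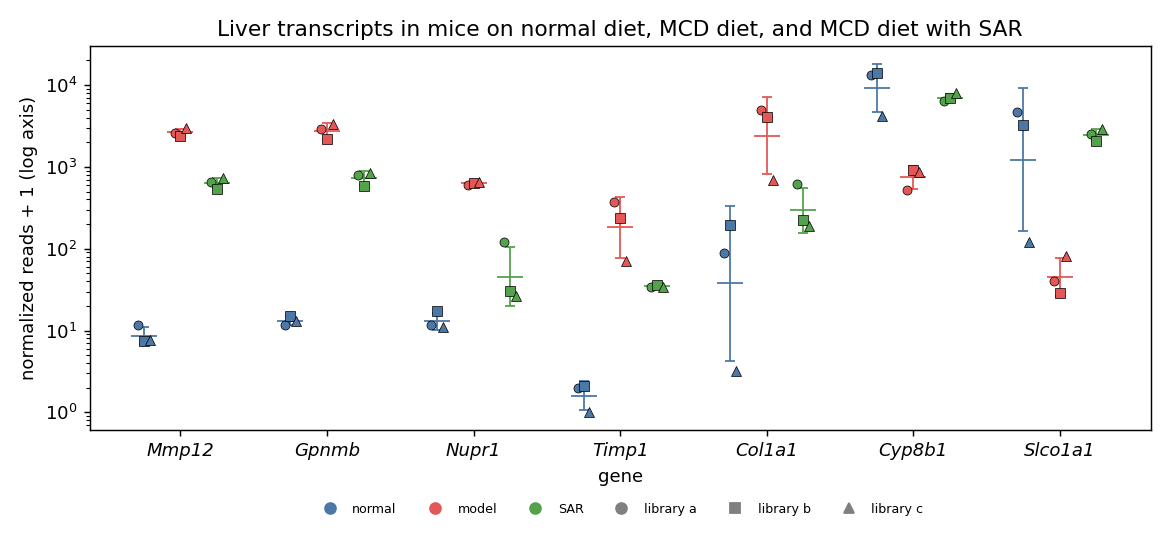
Normalised reads plus 1 (log axis, scale common to the 9 libraries) of genes named in the comparisons, with 1 point per library shaped by its letter, a line at the mean of the log2 values and bars of ± 1 SD on the log scale (n = 3). Mmp12 lay between 2411 and 2952 in the model libraries, between 538 and 722 in the SAR libraries and at or below 10.6 in the normal libraries.

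Both comparisons were then joined to count the genes that differed in the model and moved back with SAR. Of 4892 genes called in the model against the normal group and tested in both comparisons, 2611 (53.4%) were called in the opposite direction with SAR, 1549 higher then lower and 1062 lower then higher. By list, 26 of 27 changed matrix genes moved back, 15 of 16 recruited macrophage markers, 18 of 20 cell cycle genes, 15 of 16 bile acid genes and 10 of 10 male-biased genes. The numbers were 8 of 16 for T and NK cell markers, 8 of 15 for methionine and choline genes and 5 of 13 for p53 targets. Whether these shares differ between lists was not tested. The genes with the largest moves both ways were Vmn2r3, Sprr1a, Rbm24, Nrg1, Akr1c18 and Tmprss4 among those higher then lower and Mup15, Mup17, Mup12, Mup19, Mup11 and Mup9 among those lower then higher. For Sprr1a, an epithelial cornification gene, the log2 fold changes were 6.35 (SE 0.80, limma adjusted p = 0.00205) and -5.74 (SE 0.74, limma adjusted p = 0.00152).

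In 6 genes, SAR moved further in the direction of the model (19 at an unadjusted p under 0.05). By limma this count was 0 without model library a and 0 without model library b (11 and 8 at an unadjusted p under 0.05; voom with all libraries gave 5). It was 3 without SAR library b, 3 with the 9 libraries in 1 fit and 15 without normal library c and model library c, and the authors' deposited test gave 2. Chosen after their values were seen because so few genes did so, these were Cyp26a1, Ncam2, Arrdc2 and Hsd17b6, higher in both comparisons, and Cyp17a1 and Gadd45g, lower in both. Cyp17a1, a steroidogenic cytochrome, had log2 fold changes of -2.20 (SE 0.60, limma adjusted p = 0.0239) and -1.37 (SE 0.21, limma adjusted p = 0.00268), the first of which was lost without model library a (0.0890) or model library b (0.0628). Over the genes that moved back, the change with SAR undid a median of 84.1% of the change in the model (quartiles 68.4% and 104.6%), a share taken over genes picked by both tests. Of 2349 such genes tested between SAR and normal, 54 were still called. Over all genes, that comparison called 411 of 11613, a count that ran from 6 to 1087 with a library left out. The small number still called therefore does not show a full return to normal.

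The same 3 model libraries enter both comparisons, so opposite changes arise by chance. Independent lists of these sizes would share 407 genes higher then lower and 315 lower then higher, and 330 and 389 higher or lower in both. Log2 fold changes correlated at -0.85 across genes, with a covariance of -1.04. In 100 simulations of unchanged groups the correlation was -0.50 and the covariance -0.0667, so the covariance differed by -0.97 from the simulated value. The highest simulated count of genes called in opposite directions was 0. The median number of genes called there with SAR against the model was itself 0. The simulated count of opposite calls could thus hardly differ from 0 and decides nothing. With 3 model libraries no split leaving 2 in each part was possible, and part of the excess may come from the shared libraries. Without normal library c and model library c, 4437 genes moved back, whereas the count was 1011 without model library a, 942 without model library b, 1421 without SAR library b and 1689 without SAR library c.

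The SAR group was compared with the normal group to find where livers on the MCD diet with SAR still differed from normal ones. Macrophage transcripts were among the largest differences. Mmp12 stood at 6.89 ± 2.02 normalised reads in the normal group and 556 ± 78.6 in the SAR group (SD, n = 3; log2 6.16, SE 0.25, limma Benjamini-Hochberg adjusted p = 3.11e-05), and Gpnmb at 10.7 ± 1.53 and 647 ± 121 (log2 5.78, SE 0.22, limma adjusted p = 3.11e-05). Of 26 cholesterol synthesis genes 8 were higher and 18 did not pass, and the call of this list by camera did not hold with an estimated correlation (camera in limma, adjusted p = 0.405). Among the 8, Insig1 (ENSMUSG00000045294), a regulator of that pathway, went from 708 ± 115 to 2009.8 ± 211 (log2 1.51, SE 0.16, limma adjusted p = 0.0133). Cd163 (ENSMUSG00000008845), a scavenger receptor of resident macrophages, was lower, at 651 ± 238 and 65.6 ± 50.3 (log2 -3.63, SE 0.63, limma adjusted p = 0.0331).

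Of 19 recruited macrophage markers 7 were higher and 12 did not pass (14 higher adjusted over the list alone; camera adjusted p = 4.85e-10, and adjusted p = 0.405 with an estimated correlation). Beside Mmp12 and Gpnmb they included Lgals3 (log2 2.71, SE 0.34, limma adjusted p = 0.0195) and Cd63 (log2 2.55, SE 0.28, limma adjusted p = 0.0133). Of 17 Kupffer cell and macrophage markers 2 were higher and 4 lower (2 and 8 adjusted over the list alone). Lyz2 was higher (log2 1.34, SE 0.15, limma adjusted p = 0.0139). Clec4f, a marker of resident Kupffer cells, was lower, going from 1548 ± 75.4 to 726 ± 171 normalised reads (SD, n = 3, log2 -1.12, SE 0.18, limma adjusted p = 0.027). Of 16 antigen presentation genes, H2-Aa and H2-Eb1, class II genes with reads shared among related copies, were higher and 14 did not pass (6 higher adjusted over the list alone; camera adjusted p = 4.41e-05, and adjusted p = 0.492 with an estimated correlation). Of 24 inflammatory genes 3 were higher (7 higher and 1 lower adjusted over the list alone): Cxcl9, Cxcl2 and Ccl5. Timp1 had 0.595 ± 0.518 and 29.7 ± 1.05 (limma adjusted p = 0.0266) and was 1 of 2 matrix genes of 30 that were higher (3 adjusted over the list alone; camera adjusted p = 9.88e-04, and adjusted p = 0.735 with an estimated correlation). Col1a1 stood at 82.5 ± 84.3 and 298 ± 204 (limma adjusted p = 0.198) and Acta2 at 103 ± 97.1 and 48.9 ± 18.5 (0.652). Of 18 liver endothelial markers 1, the scavenger receptor Stab2, was lower, and 9 were without normal library c (4 adjusted over the list alone with all libraries; camera adjusted p = 4.41e-05, and adjusted p = 0.735 with an estimated correlation). Normal library c differed from the other normal libraries by a median of -1.03 over the endothelial markers (log2, SE 0.11) and -1.65 over matrix genes (SE 0.32). SAR library c lay a median of 0.83 (SE 0.12) above the other SAR libraries over the endothelial markers.

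Adjusted over the list alone, 16 cholesterol synthesis genes were higher with SAR than in the normal group and 2 lower, against 8 higher over all genes. Camera gave the cholesterol list an adjusted p of 1.43e-07, and adjusted p = 0.405 with an estimated correlation. In the model against the normal group, 4 of its 26 genes were higher and 4 lower (camera adjusted p = 0.397). With SAR against the model, 2 of 26 were higher (camera adjusted p = 0.0104, and 0.605 with an estimated correlation). That call was lost without model library a (camera adjusted p = 0.135) or model library b (0.0633). Nsdhl went from 122 ± 31.7 to 573 ± 188 normalised reads (SD, n = 3, log2 2.20, SE 0.27, limma adjusted p = 0.0184) and Fdft1 from 362 ± 20.3 to 809 ± 190.4 (log2 1.13, SE 0.18, limma adjusted p = 0.0297). Of 16 lipogenesis genes 3 were higher and 1 lower (4 and 2 adjusted over the list alone), with Thrsp higher (log2 1.83, SE 0.18, limma adjusted p = 0.0113), Srebf1 higher (log2 1.28, SE 0.22, limma adjusted p = 0.0333) and Acacb lower (log2 -1.61, SE 0.24, limma adjusted p = 0.0254). Fasn stood at 759 ± 64.1 and 1142 ± 197 (limma adjusted p = 0.0718). Of 24 fatty acid oxidation genes, Cyp4a32, which shares reads with near-identical relatives, and Cpt1a, from 11508 ± 1272 to 5589.9 ± 1136 (log2 -1.06, SE 0.21, limma adjusted p = 0.0387), were lower and 22 did not pass (3 lower adjusted over the list alone). Igfbp1, which encodes a growth factor binding protein, was lower (log2 -1.67, SE 0.20, limma adjusted p = 0.0184). Of 24 bile acid genes Nr0b2 was higher, from 358 ± 146 to 1236 ± 88.1 (log2 1.87, SE 0.28, limma adjusted p = 0.0258), and 23 did not pass (1 higher and 1 lower adjusted over the list alone). Cyp7a1 stood at 472 ± 67.9 and 367 ± 291 and Cyp8b1 at 9168 ± 4794 and 6188 ± 711. The 17 male-biased genes did not pass, and normal library c differed by a median of -3.88 from the other normal libraries over such genes. Without normal library c, 4 of the 17 were lower with SAR and 1 was higher. Cd36 (limma adjusted p = 0.0855), Fgf21 (0.843), Il1b (0.153), Nr1h4 (0.513), Pemt (0.348) and Plin2 (0.0918) did not pass either, and Ccl2 and Tnf were below the level needed for a test.

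Among genes named for the size of their change, Serpina6, which encodes the corticosteroid carrier of plasma, was higher with SAR than in the normal group (386 ± 271 and 2284 ± 358 normalised reads, SD, n = 3; log2 2.86, SE 0.53, limma adjusted p = 0.0341), as was Gstm3 (log2 2.61, SE 0.40, limma adjusted p = 0.0266). Cyp17a1 was lower (1470.2 ± 1422 and 89.4 ± 14.6; log2 -3.58, SE 0.58, limma adjusted p = 0.0289), and so were Cntnap1 (log2 -3.05), the leptin receptor gene Lepr (log2 -2.36), Lamb3 (log2 -2.31) and Chrna2 (log2 -2.21). Over 11613 genes tested, 411 differed between the SAR and normal groups by limma with Benjamini-Hochberg adjustment, 199 higher and 212 lower with SAR, and 213 of them by at least 2-fold. The groups did not overlap in 3857 genes (33.2%), against 10% by chance, and in simulated data for this comparison 61% of genes changed 2-fold and 90% of those changed 4-fold were called. No simulated library stood apart as normal library c did, so the higher percentage does not make this the comparison with the most power. The count was 1087 without normal library c, with 409 of the 411 genes among them, but 29 without normal library a, 8 without normal library b, 6 without SAR library a, 17 without SAR library b and 54 without SAR library c. Of the 49 genes called here among those named by the selection rule, Mmp12 and Gpnmb passed whichever library was left out, and the other 47 lost their call with at least 1 library left out.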

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

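The fits by voom, the trimmed mean of M-values, the filter on 3 libraries, the authors' deposited test and the fits without normal library c and model library c were chosen after the data had been seen. Of the 4907, 3663 and 411 genes called in model against normal, SAR against model and SAR against normal, 2929, 2285 and 213 changed at least 2-fold, and at an adjusted p under 0.01 by limma the counts were 2070, 1356 and 4. With a library left out in turn, the counts ran from 2435 (without model library b) to 5793 (without model library c) for model against normal, from 1544 (without model library b) to 5159 (without model library c) for SAR against model, and from 6 (without SAR library a) to 1087 (without normal library c) for SAR against normal. A fit with a library left out also has fewer samples. Of the 2611 genes moved back by SAR, 1675 changed at least 2-fold in both comparisons and 796 passed at an adjusted p under 0.01. Leaving out a library gave 942 (without model library b) to 3892 (without model library c), and 4437 moved back without normal library c and model library c. Over pseudocounts, no filter, recomputed or trimmed-mean size factors, the filter on 3 libraries, 1 fit of 9 libraries and voom, the counts ran from 4474 to 5314, from 3087 to 3735, from 294 to 492 and, for genes moved back, from 2212 to 2692, each within 1.5 times the count of 4907, 3663, 411 or 2611 that it varies. The authors' deposited test gave 3847 and 2696 genes, and 1956 moved back. Over 38 lists camera called 25, 32 and 13 with the preset correlation of limma and 0, 1 and 0 with an estimated correlation, while fry called 19, 19 and 2. At an unadjusted p under 0.05, camera with an estimated correlation counted 5, 3 and 3 lists. The list counts ran from 25 to 28, 29 to 32 and 11 to 17 with a library left out. In SAR against normal the median log2 fold of the acute phase response turned from -0.02 with all libraries to 0.70 (camera adjusted p = 6.77e-06) without normal library c, and that of male-biased liver genes from 0.51 to -0.53 (camera adjusted p = 0.00238). Without normal library a these medians were -0.72 and 1.30. With all libraries neither list was called (camera adjusted p = 0.903 and 0.605). Normal library c lay a median of 2.23 (log2, SE 0.86) above the other normal libraries over acute phase genes and differed by -3.88 (SE 0.87) over male-biased genes. Leaving it out thus shifts the normal means in the direction of these turns. Why this library differed stays open. No scaling that was run moved the median of all genes by more than 0.1, but each of them sets the typical gene near no change. This median therefore cannot show how the folds depend on scaling. The model libraries had larger size factors than the normal ones, yet the model group held fewer reads. Scaling by total reads would thus raise model values against normal ones, by an amount not computed. Calls of genes and lists with small folds may depend on this choice. No paired analysis was possible because the recovered libraries carry no replicate number. Over some lists, library c differed from the other libraries in the same direction in the normal, model and SAR groups. The medians were -1.65, -1.42 and -0.59 over matrix genes and 5.42, 1.16 and 0.99 over neutrophil markers (log2). Over cell cycle genes they were 0.95, -1.02 and 0.11 and did not share a direction. A fit with library c set apart in all groups was not run, so such shared shifts were not modelled. Count tests of edgeR and DESeq2 were not run on the recovered reads. Limma on log2 CPM, total-count scaling and a filter on CPM were not run, as the totals of the normal and SAR libraries were not resolved. The reads of the most abundant normal and SAR genes could not be split, which limits what can be said of Mat1a, Mup3 and Scd1.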

Other observations

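In this part, the tests of the 3 explanations for normal library c and of mixed RNA in model library c were chosen only after the result was seen, and the patterns themselves were noticed in the data. In the model group, immediate early genes rose in 12 of 19 cases against the normal group (14 adjusted over the list alone), with Atf3, Myc and Klf6 leading, and camera in limma gave an adjusted p of 1.26e-05, or adjusted p = 0.309 with an estimated correlation. Klf6, a transcription factor induced on injury, rose from 222 ± 80.5 to 1337 ± 207 normalised reads (SD, n = 3, log2 2.63, SE 0.26, limma adjusted p = 0.00107). Erythroid markers fell in 7 of 9 cases (7 adjusted over the list alone, camera adjusted p = 0.00756 and adjusted p = 0.325 with an estimated correlation), among them the globin gene Hbb-bt and Bpgm, and 4 of the 9 fell without normal library c. With SAR against the model, 2 of 9 erythroid markers rose and 1 fell (3 and 1 adjusted over the list alone), and Alas2, the first enzyme of heme synthesis in erythroid cells, rose from 176 ± 33.6 to 657 ± 54.1 (log2 1.91, SE 0.17, limma adjusted p = 4.40e-04).

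Genes of the lobule zones were counted by zone, and the zones were not tested against each other. Against the normal group, 7 of 14 periportal hepatocyte genes fell in the model and 1 rose (9 and 1 adjusted over the list alone, camera adjusted p = 0.00499 and adjusted p = 0.325 with an estimated correlation). The urea cycle gene Asl fell from 31714 ± 10692 to 4942 ± 2258 normalised reads (SD, n = 3, log2 -2.73, SE 0.41, limma adjusted p = 0.0035). With SAR against the model 8 of 15 periportal genes rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.00736 and adjusted p = 0.43 with an estimated correlation). Apoa4 led the falls and Cyp2f2 the rises (log2 1.89, SE 0.21, limma adjusted p = 0.00103). Of 15 pericentral genes 3 fell, 2 rose and 10 did not pass in the model against the normal group (4 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.13). Of 16 pericentral genes 5 rose and 1 fell with SAR (5 and 1 adjusted over the list alone, camera adjusted p = 0.00276 and adjusted p = 0.492 with an estimated correlation), with Cyp27a1 and Cyp1a2 leading the list. Model library c lay a median of 1.41 (log2, SE 0.30) above the other model libraries over the pericentral genes. Nuclear-encoded ribosomal protein genes hardly entered these changes, with 27 of 28 not passing in model against normal and 28 of 28 not passing in SAR against model.

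Normal library c differed from the other normal libraries, with neutrophil markers a median of 5.42 higher (log2, SE 0.77) and male-biased genes at -3.88 (SE 0.87). A library of an MCD-fed mouse under the wrong label was argued against, since recruited macrophage markers differed by -4.11 (SE 0.80, 19 genes) from the model libraries, and an earlier form of this test, against the other normal libraries (0.38, SE 0.65), had decided nothing. Fewer hepatocytes in the tissue, which raise the markers of all other cell types alike, were argued against, since Kupffer cell markers differed by a median of 0.55 (SE 0.20) and endothelial markers by -1.03 (SE 0.11), 1.57 apart (SE 0.23, 35 genes), and an earlier test on acute phase genes, which are part of the pattern, was dropped. A female mouse among males was argued against by 4 Y-linked genes, whose mean difference was -0.043 (log2, SE 0.20). The SEs of these tests are taken over genes, which are not independent, for a single normal library, and can understate the uncertainty. A larger share of neutrophils stays open for their markers alone, and for the whole pattern an acute inflammatory state of that animal may be a candidate explanation, not tested, as the design names no group for it.

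Clock genes differed between the libraries of each group, with Arntl lowest and Dbp highest in library c of all 3 groups. Morning genes (4) and evening genes (9), without Arntl, Dbp and Nr1d1 through which the pattern was seen, were averaged per library and centred within groups. Over the 9 libraries the 2 means had a Pearson correlation of -0.897 (permutation p = 0.0139) and a Spearman correlation of -0.767 (permutation p = 0.0231), two-sided over 216 permutations within groups, whose smallest possible p is 0.00463. Without SAR library c and model library c, the pair farthest from the median, r was -0.831 over 7 libraries. These values argue against a change of quality that moves all clock genes alike and are consistent with tissue taken at different times of day, which the labels do not record.

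Model library c had low matrix and cholangiocyte transcripts, yet its recruited macrophage markers were near those of the other model libraries. RNA of a normal or SAR mouse mixed into it would lower both alike. Among members that rose in the model group, macrophage markers differed by a median of -0.25 and matrix genes by -1.44 (log2), 1.19 apart (SE 0.31, 41 genes). The pattern was seen through these kinds of genes, and the fit that picked the members included this library. The difference thus restates the pattern and is no separate test of mixing. A smaller share of stellate cells and fibroblasts was argued against only weakly, by their markers outside the matrix list, at 0.22 (SE 0.33, 17 genes). Both SEs are taken over correlated genes of a single model library and can understate the uncertainty. Matrix genes were also low in library c of the normal group (median -1.65, SE 0.32) and of the SAR group (-0.59, SE 0.13), so the low level was not particular to the model library. Apart from the share of these cells no biological explanation was tested, and the cause stays open.

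Other splits of the same 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. For genes called by limma, 1 of 10 splits reached the real counts of 4907, 3663 and 411, and the highest other count was 0 in each comparison. At an unadjusted p under 0.05, limma counted 6316, 5330 and 3042 genes in the real split and at most 705, 1912 and 697 in another split. For lists called by camera, 4 of 10 splits reached the real 25 in model against normal (highest other 30), 1 of 10 reached 32 in SAR against model (highest other 31) and 5 of 10 reached 13 in SAR against normal (highest other 24). For genes moved back, 1 of 100 groupings of the 9 libraries, the real one, reached the real count of 2576 on the scale common to the 9 libraries. The highest other count was 85, which argues against a random grouping of the libraries as the source of the whole count. Such groupings mix libraries of different groups. They cannot tell how many of the moves come from the model libraries shared by both comparisons.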
